A study of Homo sapiens with 4 samples.

How the data were processed

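Human pluripotent stem cells (hPSC) had received a pooled lentiviral guide library and a separate lentivirus with Cas9 and mCherry, had been sorted on fluorescence and had recovered for 1 week, per the labels. In this kind of pooled screen, each construct carries a guide RNA, an EGFP gene driven by the EF1α promoter and a random guide barcode of 22 nt, so that the barcode in a cell's cDNA tells which guide the cell received. One culture was profiled as hPSC and one after induction towards ectoderm, with 0 target genes shared by their guide tables. Each gave 1 single-cell 3′ transcriptome library and 1 amplicon library that links cell barcodes to guide barcodes. The protocol text in the labels is the same for all 4 samples and mentions the induction in each; groups were taken from the sample titles. The labels name one established hPSC line for all samples. In a check of expression against that line, 2 of the 2 transcriptome libraries did not match their labels, so the identity of the line stays unsettled for all results below.

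The deposited transcriptome matrices hold raw UMI counts per gene and cell barcode, made by the authors with STARsolo and STAR on GRCh38, per the submitters' processing notes; versions, annotation release and strand setting are not given in the sources used here. The matrices list 60674 features, among them 3 added transgenes (EGFP, CAS9 and MCHERRY). The deposited amplicon tables are of another kind: they list 1 read per line, with a cell barcode, a guide barcode and the guide name that the authors matched to it, and their mismatch columns are counts of mismatched bases made by the authors. In both tables read 1 had 28 bases, of which 16 were the cell barcode, and the remaining 12 were used as the UMI. The labels name version 2 of the 10x chemistry, whereas this read length is that of later chemistry, and the conflict was not resolved. The hPSC table held 1048575 reads, which with its header makes 1048576 lines, the most that a common spreadsheet format holds, so it was treated as possibly part of a longer table.

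Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes. This removed 7 of 15333 hPSC barcodes and 0 of 16360 ectoderm barcodes. UMIs were summed over the kept cells of a library and expressed as CPM, which are counts scaled to a common library total. A log2 ratio has an exact conditional binomial 95% interval, a share an exact Clopper-Pearson interval and a sum of UMIs an exact Poisson interval. All of them cover counting error only. With 1 library per group there was no replicate check, no test between groups and no p-value. Genes were counted as differing by a rule of size: at least 20 CPM in at least 1 library and a log2 ratio of at least 1 in size. Where a library had 0 counts, a floor of 3 counts was used. The steps were tested on Poisson counts drawn from the pooled means and the totals of these libraries for 5836 genes. Of 100 genes changed 3-fold and 100 changed 6-fold, 100 and 100 met the rule, against 0 of 5636 unchanged genes. The intervals held the true ratio for 96.0%, 95.0% and 95.3% of these 3 sets. The draw follows the model of the intervals and holds no differences between cells or cultures. It therefore checks the computation and gives no error rate for genes that differ between the libraries.

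The comparisons, the rule of size, 28 gene lists and 11 lists of cell type markers were set before the data were examined. A list is given by its median log2 ratio over members at 5 CPM or more in at least 1 library and by that median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Named genes are the 15 with the highest and the 15 with the lowest log2 ratio, leaving out mitochondrially encoded genes, ribosomal protein genes and genes with no symbol, and up to 2 members from each end of each list. Other list members named in the text were chosen after their values were seen, and some members are not reported here. For targets, the targeted gene comes first, then up to 3 genes from each end at 50 CPM or more. These had a log2 ratio of at least 1 in size and the same sign in every guide with at least 20 cells. Only 4 of 113 hPSC targets and 13 of 80 ectoderm targets had 2 or more such guides. With 1 such guide, the condition on sign compares no guides. Gene positions are from GENCODE v29 on GRCh38, matched by Ensembl ID, and the authors' annotation release may differ.

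Each library was clustered alone: counts scaled to 10000 per cell and logged, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 with seed 0. Scrublet marked 4 hPSC cells (0.0261%) and 1 ectoderm cell (0.00611%), which was taken to mean that it had not worked, and doublets stayed in.

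The assignment rule set in advance asked for at least 3 UMIs of a guide and at least 80% of the cell's barcode UMIs. It left no target with 50 cells, because most cells held background barcodes. A background rule was therefore chosen after the distribution of barcode UMIs was seen and before expression by target was examined: exactly 1 guide with at least 20 UMIs. All results by target use it. Targeted genes were matched by symbol, or by a synonym that RefSeq on GRCh38.p14 gives to a single gene: 108 hPSC and 79 ectoderm targets matched by symbol and 2 and 1 by synonym, and 1 hPSC target was left unmatched. The control was cells with a non-targeting guide.

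Alternatives were all deposited barcodes, a stricter cell filter, edgeR TMM and DESeq2 size factors, CPM averaged over cells, other totals, thinning each cell to 2000 UMIs, other CPM minimums, other clustering settings, other assignment rules and other control cells. Alternatives that bring in the background rule, and own-gene ratios with all targets or under another assignment rule, were added after seeing the data. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, the last pair only for scaling factors.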

Results

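The data were 2 single-cell transcriptomes and 2 matching amplicon tables. After filtering, the hPSC library held 15326 cells with 83246015 UMIs, a median of 4807.5 UMIs and 2046 genes per cell, and the ectoderm library held 16360 cells with 91249888 UMIs, a median of 4499 UMIs and 1937 genes per cell. The median mitochondrial share was 4.18% and 3.17% of UMIs. Each state was 1 library, so every value below stands without replicates and each interval covers counting error only. The 2 libraries also carried guides for different target genes. Differences between them can therefore come from the state, the guide pool or the culture.

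The first comparison asked how the ectoderm library differed from the hPSC library. Genes of the early forebrain and of the neural plate were higher in the ectoderm library, and genes of Nodal signalling were lower, together with part of the BMP and pluripotency genes. SOX1, an early neural plate transcription factor, stood at 43.7 CPM against 0.637 CPM in hPSC (log2 ratio 6.10, 95% interval 5.71 to 6.52). OTX2, a forebrain and midbrain homeobox gene, stood at 106 against 4.71 CPM (4.49, 4.35 to 4.64). NODAL, which encodes a TGF-beta ligand, stood at 0.658 against 25.7 CPM (-5.29, -5.68 to -4.92), and the pluripotency factor NANOG at 11.6 against 178 CPM (-3.94, -4.03 to -3.85).

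Of 6244 genes at 20 CPM or more in at least 1 library, 203 met the rule of size in the higher direction and 252 in the lower. The median log2 ratio over the 6244 genes was -0.03. Among non-targeting cells alone, a comparison added after seeing the data, 168 of the 203 and 206 of the 252 also met the rule. Besides SOX1 and OTX2, the 15 highest were GREB1L (6.96), LMO1 (6.55), the retinoic acid-degrading enzyme CYP26A1 (5.87), MAP2, which encodes a microtubule-associated protein of neurons (5.25), PKDCC (4.79), OLIG3 (4.72), the secreted WNT antagonist FRZB (4.54), C11orf96 (4.42), LHX5-AS1 (4.26), LHX5, a LIM homeobox gene of the forebrain (4.25), PCDH7 (4.07), EDN1 (4.05) and IGFBP5 (3.73). Besides NODAL and NANOG, the 15 lowest were NTS (-6.60), LINC01108 (-5.66), CBR3 (-5.61), D21S2088E (-5.48), the ERK phosphatase DUSP6 (-5.05), LINC00458 (-4.38), GDF15 (-4.38), ERVH48-1 (-4.26), the BMP target ID1 (-3.70), SPRY4 (-3.62), MIR205HG (-3.56), ADM (-3.55) and B3GNT7 (-3.40). On GRCh38, SOX1 (ENSG00000182968) lies on chromosome 13 at 112067647 to 112070488, OTX2 (ENSG00000165588) on chromosome 14 at 56799905 to 56810479, NODAL (ENSG00000156574) on chromosome 10 at 70432315 to 70447951 and NANOG (ENSG00000111704) on chromosome 12 at 7787794 to 7799141. LHX5 (chromosome 12, 113462034 to 113472280, minus strand) and its antisense neighbour LHX5-AS1 (113472003 to 113480624, plus strand) overlap at their 5′ ends.

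Among the anterior neural genes, 8 of 16 members were measured and all 8 were at least 2-fold higher (median log2 ratio 2.73, percentile 100 among matched random lists). SIX3, a homeobox gene of the anterior neural plate, was at 439 against 44.0 CPM, HESX1 at 39.1 against 4.17 CPM, and ZIC2 at 672 against 210 CPM. Of the other members, RAX, LHX2 and EMX2 stayed near the floor in both libraries, with LHX2 at 0.0360 CPM in hPSC and 0.0329 CPM in ectoderm. SIX6, from the same list, stood at 46.3 against 13.8 CPM (1.75). Neural SOX and bHLH factors had a median of 1.88 (percentile 100), with 6 of 9 at least 2-fold higher: SOX9 stood at 119 against 12.7 CPM and SOX21 at 61.6 against 7.24 CPM, while SOX4 (-0.59) and HES6 (-0.65) were lower by less. PAX6, a neural progenitor marker, was at 1.20 CPM in ectoderm and 0.216 CPM in hPSC. The marker list of neural ectoderm progenitors had a median of 2.54 (percentile 100), with 7 of 8 higher and LMO3 lower (-1.15). GBX2, from the list of posterior and hindbrain genes, was lower (-2.41). The guidance and early neuronal list had a median of -0.44 (percentile 0.395), and its members ran from STMN2 (-1.28) to MAP2.

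**Figure D1:**
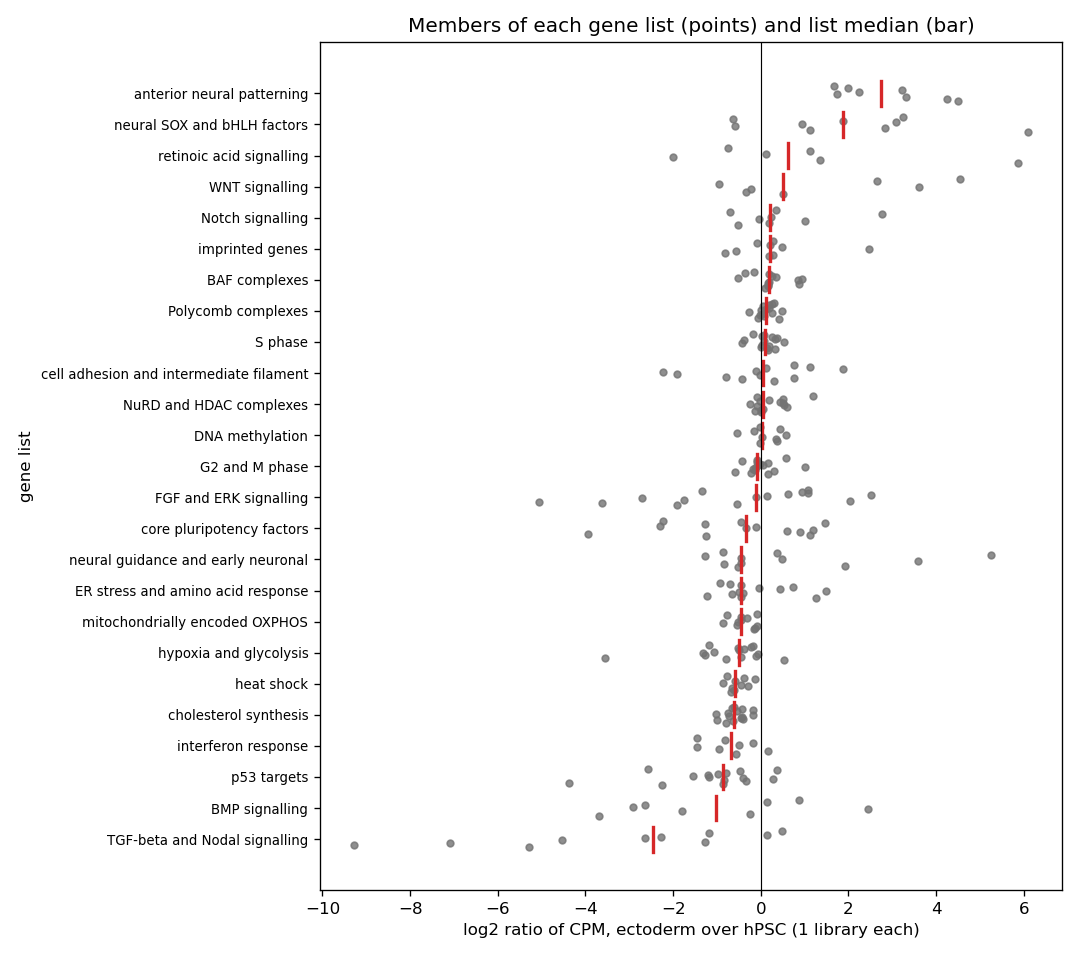
Log2 ratio of CPM, ectoderm over hPSC (horizontal axis), for the measured members of each fixed gene list with at least 6 of them (points), with the list median (bar). Anterior neural members lay at 1.67 or above, and Nodal members ran down to -9.29.

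Pluripotency genes did not move together. Of 13 measured core pluripotency factors, 3 were at least 2-fold higher and 5 at least 2-fold lower (median -0.33, percentile 1.39). POU5F1 was at 485 against 1155 CPM (-1.25), TDGF1 at 112 against 273 CPM, MYC at 22.1 against 103 CPM and DPPA2 at 4.34 against 21.2 CPM. SOX2, shared by pluripotent and neural cells, was at 516 against 236 CPM (1.13), SALL4 at 424 against 184 CPM and UTF1 at 120 against 43.5 CPM. DPPA4 (-0.10) and DNMT3B (0.34) differed by little. The pluripotent stem cell markers had a median of -1.10 (percentile 0), with 7 of 13 lower and 0 higher by 2-fold. Of the naive pluripotency genes only DPPA5 was measured (-2.90).

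TGF-beta and Nodal genes had a median of -2.46 (percentile 0), with 8 of 10 at least 2-fold lower. LEFTY1, a Nodal antagonist and target, had 1 UMI in ectoderm against 570 in hPSC (-9.29, -14.59 to -6.80) and LEFTY2 had 4 against 494 (-7.08, -8.96 to -5.72). GDF3 (-4.54), SMAD7 (-2.64) and SKIL (-2.27) were also lower, whereas FOXH1 (0.14) and FST (0.48) were not. BMP genes had a median of -1.03 (percentile 0), with 4 of 8 at least 2-fold lower and 1 higher: ID1 and BAMBI (-2.92) were at the low end and ID4 (2.44) at the high end. In the FGF and ERK list (median -0.10, percentile 25.7), 6 genes were at least 2-fold lower, among them DUSP6, SPRY4 and ETV5 (-2.72), and 4 were higher, among them the ligand FGF8 (2.51) and DUSP4 (2.04). WNT genes had a median of 0.50 (percentile 99.6), with 3 of 7 at least 2-fold higher: among the antagonists SFRP1 was at 917 against 75.3 CPM and SFRP2 at 357 against 690 CPM (-0.95). Hedgehog genes had a median of 1.32 (percentile 99.9), with 2 of 4 at least 2-fold higher, among them PTCH1, the receptor, at 92.3 against 25.9 CPM. Retinoic acid genes had a median of 0.62 (percentile 99.9), from CYP26A1 down to ALDH1A3 (-2.00). Notch genes had a median of 0.21 (percentile 89.3), with 2 of 8 at least 2-fold higher: HES1 was at 131 against 19.3 CPM, while HEY2 (-0.69) and NOTCH1 (-0.52) were lower by less.

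Genes induced by p53 were lower in the ectoderm library (median -0.86, percentile 0), with 6 of 15 at least 2-fold lower, among them GDF15, PLK2 (-2.57) and the cell cycle inhibitor CDKN1A (-2.26), while TP53INP1 stood at 0.37. All 15 cholesterol synthesis genes had ratios below 0 (median -0.61, percentile 0), from CYP51A1 (-1.03) to LSS (-0.17), though CYP51A1 stood at 0.71 among non-targeting cells alone, from 8 ectoderm and 6 hPSC UMIs. Heat shock genes (median -0.60, percentile 0.01), hypoxia and glycolysis genes (-0.49, percentile 0.06), interferon genes (-0.69, percentile 0), ER stress genes (-0.45, percentile 0.28) and mitochondrially encoded genes (-0.45, percentile 0.19) also had medians below 0. LDHA, the lactate dehydrogenase gene, stood at 377 against 940 CPM and HSPD1 at 795 against 1454 CPM, whereas DDIT4 stood at 149 against 53.3 CPM. S phase genes had a median of 0.10 (percentile 90.7), from PCNA (-0.43) to TYMS (0.53), and G2 and M phase genes -0.08 (percentile 43.5), from CCNB1 (-0.60) to BUB1 (1.02). The medians of chromatin lists were DNA methylation 0.03 (percentile 63.9), Polycomb 0.12 (86.9), NuRD and HDAC 0.04 (73.0) and BAF 0.18 (96.4), in which ARID1B (0.95) and SMARCC2 (0.86) were highest. Imprinted genes had a median of 0.20 (percentile 94.6), with NNAT at 232 against 41.7 CPM and SNRPN at 402 against 704 CPM. In the adhesion and filament list (0.05, percentile 81.7), KRT18 (-2.22) and KRT8 (-1.90) were lowest and FABP7 (1.87) highest.

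Markers of other cell types were mostly low. Neuron markers had a median of -1.22 (percentile 0.7, from 3 genes), neural crest -0.87 (0.435, from 5), amnion -1.42 (0.22, from 4), mesenchyme -1.16 (0.11, from 4) and surface ectoderm 0.42 (94.2, from 3). Amnion markers ran from BAMBI to IGFBP3, which was higher (2.91) at 10.6 against 1.42 CPM. Among placode markers SIX4 stood at 30.9 against 34.5 CPM, among mesoderm markers KDR at 3.17 against 29.7 CPM, and 0 of 12 endothelial and blood markers were measured. HHEX, counted with endoderm but also used in other tissues, stood at 51.4 against 8.31 CPM.

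Within each library the cells fell into 3 clusters in hPSC, with 4671, 7042 and 3613 cells, and 6 in ectoderm, with 5630, 2943, 5700, 1336, 322 and 429 cells. The clusters are numbered from 0 and carry no cell type name. Pluripotent stem cell markers summed to between 3909 and 4110 CPM across the hPSC clusters, and neural ectoderm progenitor markers to between 474 CPM (cluster 3) and 1075 CPM (cluster 1) across the ectoderm clusters. Median depth also differed between ectoderm clusters, from 3011 UMIs in cluster 1 to 6985.5 in cluster 2. So did the cell cycle: G2 and M phase genes summed to 1979 CPM in cluster 1, 4692 CPM in cluster 2 and 6091 CPM in cluster 3, and in hPSC to 5969, 1737 and 2349 CPM in clusters 0, 1 and 2. Mitochondrially encoded genes summed to 52503 CPM in ectoderm cluster 4 and 6094 CPM in cluster 5.

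The amplicon tables link cells to guides, so that cells of a target can be compared with other cells of the same library. The hPSC table named 113 target genes and 23 non-targeting guides, and the ectoderm table had 80 target genes and 16 non-targeting guides, with 0 target genes in both. No target could therefore be followed from hPSC to ectoderm. By the rule set in advance, 1283 of 15326 hPSC cells (8.37%, 7.94% to 8.82%) and 68 of 16360 ectoderm cells (0.416%, 0.323% to 0.527%) were singly assigned. Pairs of cell and guide formed a low group of 1 to a few UMIs and a separate group in the bins that start at 64 and 128 UMIs, and pairs with under 20 UMIs held 52.97% of hPSC and 69.4% of ectoderm amplicon UMIs. With exactly 1 guide at 20 UMIs or more, 2915 hPSC cells (19.02%, 18.4% to 19.7%) and 3686 ectoderm cells (22.5%, 21.9% to 23.2%) were assigned. Non-targeting guides made up 7.27% of these in hPSC (6.36% to 8.28%) and 4.31% in ectoderm (3.68% to 5.02%).

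**Figure D2:**
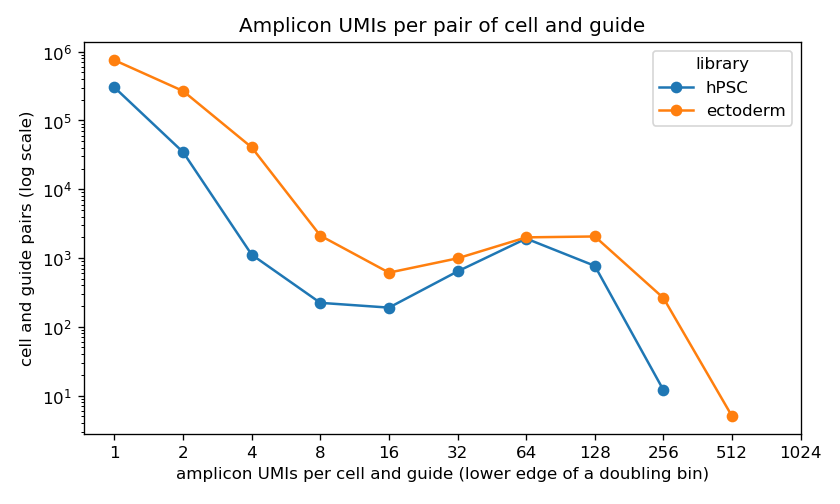
Number of pairs of cell and guide (log scale) by amplicon UMIs in doubling bins, for each library. A low group falls away towards 16 UMIs, where hPSC has 190 pairs and ectoderm 613, and a higher group follows, with 1918 hPSC pairs in the bin that starts at 64.

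The largest ectoderm targets were VRTN with 135 cells, PDF with 120, RPS19BP1 with 115, CHID1 with 98, MRPS12 with 96, ZNF593 with 95, NUP98 with 94, ALDH4A1 with 83, ACAD8 with 81 and MDC1 with 81. In hPSC, SH3GL1 had 73 cells, CMBL 72 and PGLS 68. The median was 18 cells per target in hPSC and 37 in ectoderm, and 8 and 28 targets reached 50 cells.

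Targeted genes were close to their level in control cells. Over the 28 ectoderm targets with 50 cells, 630 UMIs of the targeted genes were counted (582 to 681) where non-targeting cells predicted 676, a ratio of 0.933 (0.861 to 1.01). Over the 8 hPSC targets, 165 were counted (141 to 192) against 158, a ratio of 1.04 (0.891 to 1.22). These intervals leave out the counting error of the control cells. The sums give more weight to genes with more UMIs, and most of the shortfall in ectoderm came from SOX2. SOX2 was lower in the 54 ectoderm cells with its guides, at 437 against 565 CPM in non-targeting cells (log2 ratio -0.37, -0.65 to -0.10) and 521 CPM in all other singly assigned cells (-0.25, -0.51 to -0.0097). YAP1 had 4 UMIs in its 47 hPSC cells where all other singly assigned cells predicted 10.6, TAGLN 11 where 19.8 were predicted, and TIMM10 had 2 in its 17 ectoderm cells where 7.36 were predicted. In the other direction, MT1H had 57 UMIs against 40.7 and UGDH 11 against 5.07, both in hPSC. Among targets with at least 5 predicted UMIs, the ratio lay below 1 for 43 of 74 in hPSC and 30 of 53 in ectoderm, and below 0.5 for 2 in each. The whole interval lay below 1 for only 2 in hPSC and 2 in ectoderm, and above 1 for 2 and 0. The single targets named here are among these 74 and 53, so their values are not read as detected knockouts. UMIs come from transcript 3′ ends, so an edited transcript that is not degraded may still be counted. Where the guides' target sites lie was not examined.

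**Figure D3:**
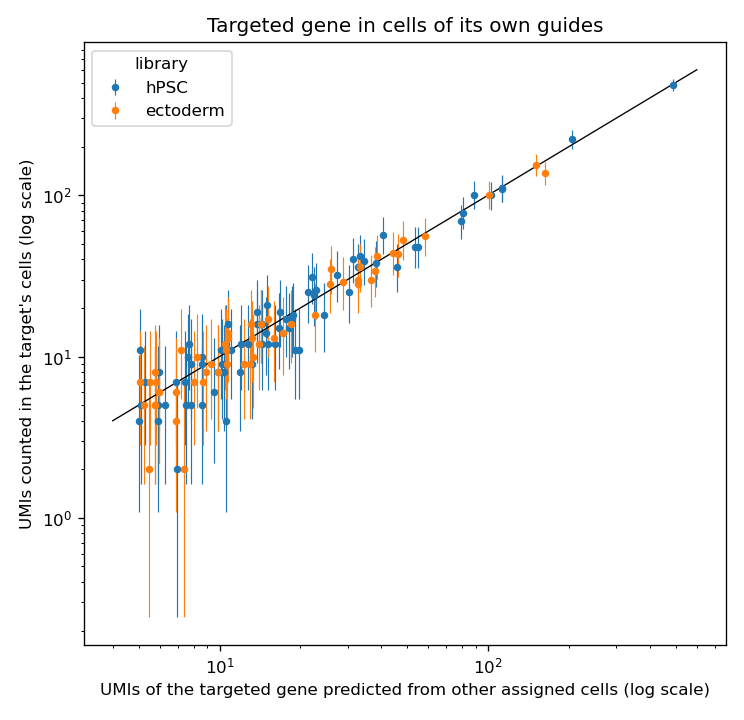
UMIs of each targeted gene counted in cells with its guides, with exact 95% Poisson intervals, against the number predicted from all other singly assigned cells (both axes log scale), for targets with at least 5 predicted UMIs. The line marks equal values, and the points lie along it in both libraries.

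Other genes in cells of a target were compared with non-targeting cells by the median size of their log2 ratio, set against that from counting error alone. Over targets the median was 0.18 in hPSC, where counting error gave 0.17, and 0.17 in ectoderm, where it gave 0.16. The first value over the second ran from 1.04 to 1.22 in hPSC, highest for COA3, and from 0.959 to 1.21 in ectoderm, highest for SOX2. In SOX2 cells, SOX1 had 6 UMIs, or 19.2 CPM against 58.9 CPM in non-targeting cells (-1.62, -3.12 to -0.41) and 43.7 CPM in the whole ectoderm library, with ANKRD17 (-1.80) and CRBN (-1.73) also low and C1orf109 (1.70), DPY19L3 (1.61) and METTL8 (1.55) high. In NUP98 cells, CWC15 was lowest (-1.37) and ABRAXAS1 highest (1.37). TAGLN was high in cells of DHRS4 (1.68), PCCA (1.63), VRTN (1.59), MDC1 (1.29), ALDH4A1 (1.25) and RPS19BP1 (1.03), all against the same non-targeting cells, in which it had 29 UMIs, or 28.5 CPM. PCCA had only 1 guide with 20 cells, so guides could not be compared there. TAGLN stood at 85.8 CPM in VRTN cells and at 39.3 CPM in the whole ectoderm library. In hPSC it was high in cells of PGLS (1.46, 1.01 to 1.90), at 204 CPM against 74.4 CPM in non-targeting cells and 78.3 CPM in the whole library. These genes were picked from the ends of many, and the intervals leave out differences between cells.

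Shares of cells per cluster were compared between each target and non-targeting cells. The largest difference was 14.1 percentage points in hPSC, for KRT86 in cluster 1 (27.5%, 15.9% to 41.7%, against 41.5%, 34.8% to 48.5%). In ectoderm it was 13.0 points, for THOC3 in cluster 2. The target changed with the settings: with guides at 10 UMIs the largest was 16.7 points in hPSC, for YAP1, and 13.1 points in ectoderm, for CHID1, and with clusters at resolution 1.0 it was 12.6 points in hPSC, for KRT86, and 19.97 points in ectoderm, for LAMB1. In ectoderm cluster 3, targets had a median of 6.21%, and 25 of 28 lay below the 11.9% of non-targeting cells (7.35% to 18.0%), while the whole library had 8.17%. The lowest there was LAMB1 at 0% (0% to 5.60%) and the highest SOX2 at 20.4% (10.6% to 33.5%).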

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

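Of the tests in this part, those on free EGFP RNA, on reads missing from the hPSC table, on background barcodes and on the cap for free RNA were chosen only after the result was seen.

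Mitochondrially encoded OXPHOS genes were higher in targeting than in non-targeting cells of hPSC (log2 ratio 0.048, 0.034 to 0.062) and lower in ectoderm (-0.047, -0.064 to -0.030), and the difference between the libraries was not tested. These intervals leave out differences between cells, and the sum of these genes ran from 6094 CPM in ectoderm cluster 5 to 52503 CPM in cluster 4. The range over single non-targeting guides was not computed for this list, so differences this small are not resolved. CAS9 had 493 UMIs in hPSC and 427 in ectoderm, and MCHERRY 30 and 33, in features the comparisons do not use. Guide barcodes found in both read tables numbered 6 of 4176, and 0 of them carried the same guide name in both.

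Most cells had no guide above background, although EGFP UMIs were seen in 93.1% of hPSC and 94.1% of ectoderm cells. Free EGFP RNA in cells that carry no construct is argued against, since cells with no guide held 72.7% (hPSC) and 80.5% (ectoderm) of the EGFP CPM of singly assigned cells. Reads missing from the hPSC table could not lower the ectoderm share of cells with a guide, so they are not the cause there. Their effect on the hPSC share stays open. The ectoderm share was 1.34 times the hPSC share. The libraries also differ in state, guide pool and culture, so this ratio cannot decide. Too few amplicon reads per cell stays open and cannot be told apart from other losses: in cells at or above percentile 90 of EGFP UMIs, 41.4% of hPSC and 59.2% of ectoderm cells (56.8% to 61.5%) had a guide, and the ectoderm interval crosses the limit of 60% set in advance. Guide barcodes missing from the authors' reference list may also add to it and were not tested, and no biological explanation was tested.

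Targeted genes were not lower in their own cells, taken over all targets. Background barcodes assigned as guides stay open. At 40 or more barcode UMIs the ratio was 0.986 in hPSC (0.947 to 1.03) and 0.972 in ectoderm (0.919 to 1.03). Both lower bounds lay above 0.8, the limit chosen against this cause. The stricter rule left 2760 singly assigned hPSC cells where 20 UMIs gave 2915, and 3484 ectoderm cells where it gave 3686. With so few cells taken out, the test could hardly move the ratio and cannot decide. As far as a CAS9 UMI marks a cell with the gene, cells without Cas9 are argued against as the whole cause. The 191 cells with a CAS9 UMI had a ratio of 1.07 (0.924 to 1.24), past the limit of 0.8 set in advance against this cause. Free RNA could place a CAS9 UMI in a cell without the gene, but cells with 0 EGFP UMIs (6.90% of hPSC and 5.88% of ectoderm cells) cap it at 14.6% and 17.4% of EGFP UMIs. The share of free RNA among CAS9 UMIs was not measured. With the larger EGFP share in its place and a ratio of 0.7 taken for cells with the gene, this cause would need a ratio under 0.752. Edits that leave the transcript in place, and guides that did not cut, stay open and were not tested.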

How the results depend on the processing

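Alternatives that bring in the background rule were chosen only after the data were seen, as were own-gene ratios with all targets or under another assignment rule; the others were planned. The genes meeting the rule of size numbered 203 to 264 higher and 235 to 269 lower under the other scalings, cell filters and thinning, but 425 and 522 at 5 CPM, 1924 and 2674 with only 10 UMIs required, 636 and 587 in cells assigned by the rule set in advance, and 341 and 404 in non-targeting cells, where fewer cells or lower counts enter by construction. In cells assigned by that rule, ALDH1A3 (0.35), BAMBI (0.20), ETS1 (0.16), LEFTY1 (0.80) and LEFTY2 (1.59), among others, had a ratio of the other sign, made by the floor of 3 counts: the 68 ectoderm cells held 0 UMIs of each gene named, so these are not measured changes. In non-targeting cells CYP51A1 (0.71, from 8 ectoderm and 6 hPSC UMIs) and DDIT3 (-0.068, from 7 and 9) changed sign; the cause was not tested. Clusters numbered 8 in hPSC at resolution 1.0 and 2 in ectoderm at 0.25. Singly assigned shares in hPSC and ectoderm were 11.5% and 1.88% at 1 UMI, 19.8% and 14.3% with a top guide at 50% of UMIs, 0.215% and 0.0428% at 95%, and, by the background rule, 19.02% and 22.5% at 20 UMIs, 19.7% and 23.3% at 10, and 18.0% and 21.3% at 40; the non-targeting share in hPSC was 7.27% at 20. The ectoderm own-gene log2 ratio was 0.075 with a top guide at 50% and 0.12, from 15 UMIs, with the rule set in advance, all targets and all other cells as control; the cause was not tested. Over the single genes reported and the lists, 1246 values stayed within their counting interval, 1236 with the same sign and 10 with the other. Another 343 left it with the same sign, 24 left it with the other sign from a ratio under 1 in size, and the 7 above had the other sign from a larger one. Leaving out Scrublet calls was not run, since the caller had not worked, and the planned results by target at 10 UMIs and 80% gave no value, since no target reached 50 cells. No paired analysis was possible because each group has 1 library.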

Other observations

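The comparisons in this part were not planned, and the groups of targets were chosen only after cells per target were seen.

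Non-targeting hPSC cells held 1070 CPM of p53 target genes and targeting cells 1177 CPM (log2 ratio 0.14, 0.06 to 0.22), with 963 to 1256 CPM over 11 single non-targeting guides. In ectoderm the values were 634 and 599 CPM (-0.08, -0.20 to 0.03). Cells with no guide above background held 1203 CPM in hPSC and 599 CPM in ectoderm, in both nearer to targeting than to non-targeting cells. Further hPSC lists, among them WNT and retinoic acid genes, also had intervals that left out 0. Anterior neural genes in non-targeting and targeting cells summed to 352 and 315 CPM in hPSC (-0.16, -0.30 to -0.02) and to 1476 and 1547 CPM in ectoderm (0.07, -0.01 to 0.14). Neural ectoderm progenitor markers summed to 165 and 148 CPM in hPSC (-0.16, -0.36 to 0.05) and to 770 and 841 CPM in ectoderm (0.13, 0.03 to 0.23). In cells with no guide above background, anterior neural genes summed to 327 CPM in hPSC and 1538 CPM in ectoderm. Neural ectoderm progenitor markers summed there to 155 and 839 CPM. For both lists these sums lay nearer to targeting than to non-targeting cells. Single non-targeting guides ran from 230 to 488 CPM (hPSC) and from 1283 to 1548 CPM (ectoderm) for the first of these lists, and from 37.9 to 263 CPM and 670 to 898 CPM for the second; these guides had 10 to 36 cells each, and the ranges include their counting error.

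In hPSC, 12 targets of translation and the proteasome, from EIF5B with 1 cell to VARS with 46, had a median of 13 cells, and 7 keratin-family targets, which had 0 UMIs of their own genes in these cells, had a median of 42 (17 to 51). The first group also had fewer guide barcodes, a median of 13 against 32, and cells per barcode were 1.02 and 0.947. Guides per target in the read table also differed: EIF5B had 2 and VARS 4, while each keratin-family target had 4. Over all 113 hPSC targets the median was 18 cells. How many plasmids of each guide entered the pool was not analysed here.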
